A study of Gambusia holbrooki with 30 samples.

How the data were processed

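Total liver RNA was labelled with Cy3 and hybridised to a custom Agilent array with 15740 spots, 1 sample per array, per the labels' protocols. The deposited scanner files hold background-corrected spot intensity (processed signal), mean and local background intensity and spot flags, made with Agilent Feature Extraction, version 10.1.1.1 per the file headers and version 9.1 per the submitters' processing notes. The value table deposited by the authors is on a log2 scale. Its 14954 rows equal log2 of the processed signal within 1e-06, with no scaling between arrays, and its 1428 empty cells are all spots with an outlier flag. It leaves out the 25 probes spotted 10 times.

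Groups were taken from the labels (sex and exposure). The log2 processed signal of each array was set relative to the array's 75th percentile over 15204 non-control spots. Spots flagged as outliers were left out, between 5 and 259 per array, saturated spots were kept, and spots of one probe were averaged. A probe was tested if it was well above background on at least 3 arrays of at least 1 of the 8 groups, which left out 5804 probes. Means of the 8 groups were fitted to all 30 arrays with limma 3.58.1 (R 4.3.3), giving 22 residual degrees of freedom, and each of the 16 comparisons was adjusted by Benjamini-Hochberg with a threshold of 0.05. Where a probe was not well above background on any array of the dimmer group, the fold is a bound: the mean of the brighter group against, per array, the higher of the lowest signal among probes well above background and the probe's own.

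Slides were numbered in order. Females were on slides 1 and 4 and males on slides 2 and 3, and the 2 scan days held 1 sex each. Correlations between arrays lay between 0.799 and 0.968, and no pair was counted as a duplicate.

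The fit was tested on simulated data made from shuffled residuals of all 9175 probes, with 200 probes changed in one group. For females after levonorgestrel against control, 13.4% of 2-fold, 58.2% of 4-fold and 92.4% of 8-fold changes were recovered, with 4 false calls. For males after the mixture against control these were 4.5%, 38.8% and 75.8%, with 0 false calls. False calls were not evenly spread: the simulation of female levonorgestrel against mifepristone made 50 and that of male levonorgestrel against control 15. Whole arrays were shuffled, which keeps the correlation between probes, and in those simulations the calls exceeded the nominal error rate. The shuffle ran across both sexes, with a single draw per comparison, so the spread of these figures between draws is not known. Simulated male groups could hold residuals of female arrays, so the male figures do not describe male arrays alone. If males vary more, recovery in males is overstated, and the reverse in females.

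The choices above, the naming rule and the alternatives were fixed before the data were examined, except where the text says otherwise. The naming rule allowed, without gene names, at most 2 probes that rose and 2 that fell per comparison, the largest changes among called probes well above background on every array of at least 1 compared group. The 27 gene lists fixed beforehand matched 0 probes, so no list was tested. Alternatives were normexp (offset 50) with quantile normalization, quantile normalization, the value table, no filter, a filter for probes well above background on all arrays (4025 probes), slide or replicate number as a block, each slide alone, the arrays of 1 sex, trended and robust variances, and each array left out. Added after seeing the data were another percentile, array weights, at least 2 unflagged spots per group, removal of the 3 arrays with under 45% of probes well above background, and that share as a covariate.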

Results

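Liver RNA of wild-caught adult Eastern mosquitofish (Gambusia holbrooki, a small livebearing fish) was measured on 30 one-colour arrays after 48 h in water with levonorgestrel (a synthetic progestin), mifepristone (an antagonist of the progesterone receptor), a mixture of both, or vehicle alone. Each compound was given at 100 ng per L. Each of the 4 female groups had 4 arrays. Males exposed to levonorgestrel or to mifepristone also had 4 arrays each, and male controls and males exposed to the mixture had 3 each. The array carried 14979 distinct probes of 60 bases, and 9175 entered the tests. The files pair no probe with a gene name, so probes are given by their identifiers and no pathway or cell type could be read from them. The number of arrays limits the precision of every value. Labels call the samples of a group replicates without stating that each came from a separate fish, so p-values measure the spread between these samples.

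Detection differed between arrays more than between groups. The share of probes well above background was 53.2% ± 3.8 (SD, n = 4) in female controls and 54.5% ± 18.9 (SD, n = 3) in male controls. Among male controls it ran from 37.6% to 74.9%. The signal at the 75th percentile of an array lay between 91.4 and 435.0.

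**Figure D1:**
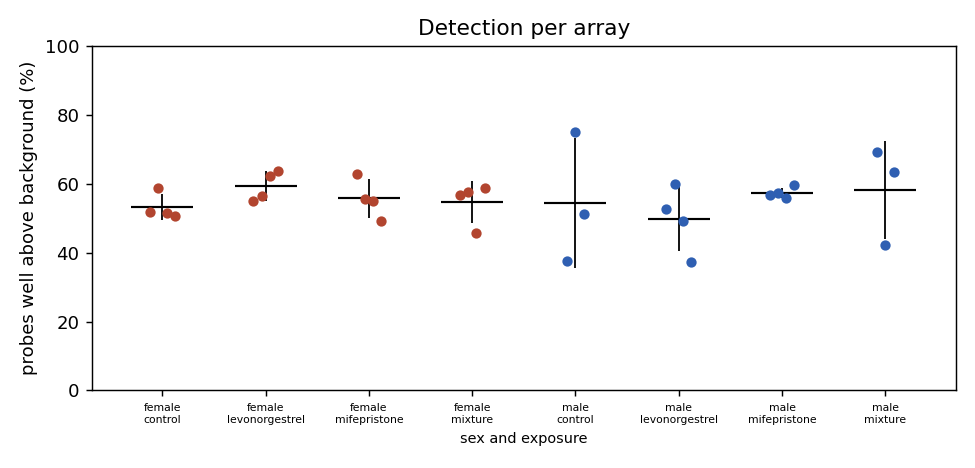
Share of probes well above background (vertical axis, percent) for each array, by sex and exposure (horizontal axis, females red, males blue); points are arrays, horizontal bars the group mean and vertical bars 1 SD. Male controls spread from 37.6% to 74.9%, against 50.6% to 58.9% in female controls.

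The comparison of female with male controls asked which liver transcripts differed between the sexes without exposure. Of the tested probes, 313 differed (limma, Benjamini-Hochberg adjusted p under 0.05), 110 higher in females and 203 higher in males. For 84 of them no array of the dimmer sex was well above background, so that their fold is only a bound. With those probes at their bound and the others at their fitted fold, the median difference was 4.08-fold, and 159 differed by more than 4-fold. MosFish_UF_21185 was well above background on all 3 male control arrays and on 0 of 4 female control arrays. Its mean was -0.61 ± 1.83 (SD, n = 3) in males and -5.10 ± 0.17 (SD, n = 4) in females. With the main scaling the bound on the means was 6.3-fold (log2 2.66) higher in males, which is not a confidence limit. The measured log2 difference was -4.49 (limma adjusted p = 9.07e-05), taken against female values not well above background. With normexp it was -1.59 (limma adjusted p = 0.0147), smaller than that bound. The probe reads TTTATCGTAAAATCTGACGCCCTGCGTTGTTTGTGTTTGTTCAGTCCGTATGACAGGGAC. MosFish_UF_12541 was lower in females by a log2 difference of -6.63 (SE 1.59, adjusted p = 0.0191), but its male control values ran from 1.64 to 8.88. The difference was -4.49 without male control 1 (adjusted p = 0.133), -7.29 without male control 3 (adjusted p = 0.0507) and -6.17 without female control 4 (adjusted p = 0.0568). In exposed fish it was -1.40 (adjusted p = 0.257). MosFish_UF_23531 was higher in females by 4.80 (SE 1.18, adjusted p = 0.0214). The difference was 2.47 without male control 2 (adjusted p = 0.121), 5.01 without male control 3 (adjusted p = 0.0671), 4.66 without female control 1 (adjusted p = 0.0542) and 2.49 with normexp (adjusted p = 0.0721). In exposed fish it was 2.13 (adjusted p = 0.0186). MosFish_UF_14833 was higher in females by 6.26 (SE 0.74, adjusted p = 0.000535), against 1 unflagged male control spot at 2.62, which was assumed to vary like the other groups. The unflagged spots of exposed males lay higher, from 4.55 to 7.51.

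The number of sex differences depended on single arrays: it was 73 without male control 3 and 531 without male control 2. Quantile normalization gave 308 probes, 146 higher and 162 lower in females. Normexp background correction with quantile normalization gave 180, 41 higher and 139 lower. Every slide and every scan day held 1 sex only, so sex and scan day cannot be told apart. With slide as a random block, 279 probes differed. That fit used a single correlation within slides (0.035) for all probes. Since each slide held 1 sex, it cannot separate sex from slide.

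In exposed fish, which share no array with the controls, 312 of the 313 probes were measured. All 312 had the same direction, and 298 passed the threshold. Over all probes tested in exposed fish, 2163 of 9168 passed it. The spread was pooled over all 8 groups, control arrays included, so the 298 are not independent of the control comparison. Exposed fish also shared slides and scan days with the controls of their sex, so these values do not separate sex from slide or scan day. Among probes not called in the controls, 75% also had the same direction in exposed fish. The probes were selected in the control arrays, and their measured differences were smaller in exposed fish, with medians of 1.54 against 2.23 (log2) for those higher in females and -1.78 against -2.38 for those higher in males. Over all 4 treatments, a comparison added after the data were seen, 2818 probes differed between the sexes, 1417 higher in females and 1401 higher in males. With 78 of them at a bound and the others at their fitted fold, the medians were 1.99-fold and 2.11-fold. MosFish_UF_19763 was lower in females by a log2 difference of -4.04 (SE 0.20, adjusted p = 1.62e-13), with a mean of -2.93 ± 0.55 (SD, n = 16) in females and 1.1 ± 0.47 (SD, n = 14) in males, and the sexes did not overlap. MosFish_UF_10448 was higher in females by 4.84 (SE 0.81, adjusted p = 1e-04), with 16 female and 11 male spots unflagged. Its values overlapped between the sexes, from 5.62 in females and from -3.87 to 6.34 in males, and the control comparison alone did not call it (adjusted p = 0.0678).

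**Figure D2:**
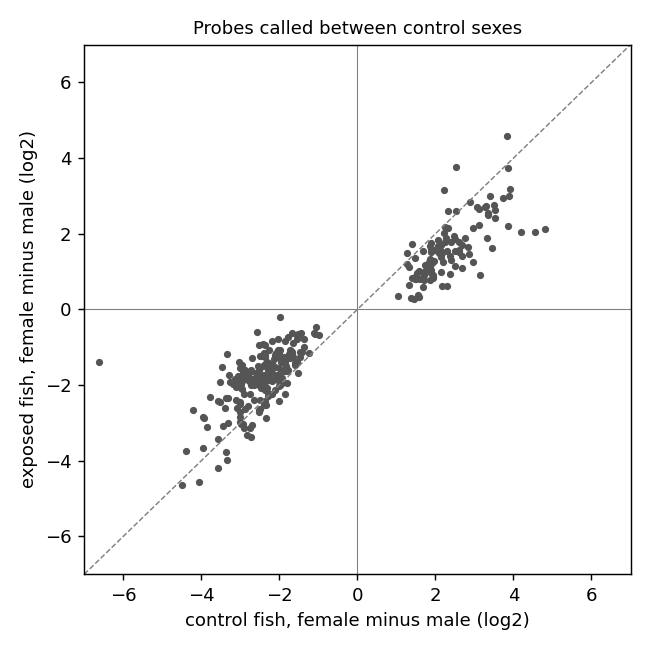
Log2 difference, female minus male, of the probes called between control sexes, in control fish (horizontal axis) and in exposed fish (vertical axis); each point is a probe and the dashed line marks equal values. The 312 probes measured in both lie in the quadrants of equal sign.

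The comparisons of each exposure with its control asked which transcripts levonorgestrel, mifepristone or the mixture changed within each sex. In females no probe passed the threshold under any exposure with limma. At an unadjusted p under 0.05 there were 214 probes after levonorgestrel, 209 after mifepristone and 333 after the mixture, of 9175 tested. Most female control arrays were on slide 1 and most female mixture arrays on slide 4, so slide and exposure are partly mixed. With slide as a block no probe passed in females either. The numbers at an unadjusted p under 0.05 were then 234, 304 and 275 in the same order (limma). In males no probe passed after levonorgestrel or mifepristone, with 901 and 234 probes at an unadjusted p under 0.05. After the mixture 1 probe passed in males, MosFish_UF_12318, lower by a log2 difference of -7.32 (SE 0.72, adjusted p = 0.000588). That value rests on 1 unflagged male mixture spot at 0.19, assumed to vary like the other groups, and 2 unflagged male control spots. It was not tested when at least 2 unflagged spots per group were required, and the count was then 0, with 371 probes at an unadjusted p under 0.05. With the arrays of males alone the difference was the same, but its adjusted p was 1 and the count was 0, with 262 probes at an unadjusted p under 0.05 (limma).

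These counts do not show that the exposures left the liver unchanged. The 95% interval of the difference had a median half-width of 0.98 (log2) for each female exposure and from 1.06 to 1.13 for the male ones. It excluded a change of 4-fold or more for 82.8% of probes after levonorgestrel in females and for 71.9% in males. After mifepristone it did so for 85.2% in females and 79.5% in males, and after the mixture for 82.4% and 73.8%. The fit behind these intervals held no slide term, and slides were shared unevenly between exposed and control arrays. A change of 2-fold or more was excluded for 24.8% of probes after levonorgestrel in females and for 14.9% in males. Of the 9175 tested probes, 4025 were well above background on all arrays. Where a probe was not well above background in either compared group, its interval describes the signal and need not bound the change in transcript. The spread of each probe was pooled over both sexes, so interval widths differ between the sexes only through the number of arrays. Each array's median correlation with its own group was 0.847 to 0.874 in male controls and 0.917 to 0.933 in female controls. If males vary more, the male intervals are too narrow and the male shares too high, and the reverse in females.

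Levonorgestrel and mifepristone were compared at the same concentration and time. No probe differed in females, with 507 at an unadjusted p under 0.05, and none in males, with 722 (limma). The interval of the difference, with the spread pooled over both sexes, excluded 4-fold or more for 80.6% of probes in females and 79.0% in males.

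The mixture was compared with each compound alone, to ask what the second compound added. In females 3 probes were higher after the mixture than after levonorgestrel. MosFish_UF_13241 was 0.82 ± 1.03 (SD, n = 4) after the mixture and -5.12 ± 1.11 (SD, n = 4) after levonorgestrel, a log2 difference of 5.94 (SE 1.02, limma adjusted p = 0.0342). It was well above background on all 4 mixture arrays and on 1 of 4 levonorgestrel arrays, and the difference was 2.57 with normexp (limma adjusted p = 0.0647) and 5.79 with quantile normalization (limma adjusted p = 0.0608). MosFish_UF_15484 was 3.30 ± 0.72 (SD, n = 4) and -0.41 ± 0.84 (SD, n = 4), a difference of 3.71 (SE 0.70, limma adjusted p = 0.0425), 3.11 with normexp (limma adjusted p = 0.0621), 3.61 with quantile normalization (limma adjusted p = 0.0793), 3.71 with no filter (limma adjusted p = 0.0649) and 3.66 with the percentile over probes well above background on all arrays (limma adjusted p = 0.0620). Without the 3 dim arrays the adjusted p was 0.109 for both probes (limma). Those arrays were all male, so their removal changed the pooled spread and not the compared values. Leaving out any 1 of these 8 arrays left 0 or 1 probe. The arrays of females alone gave 0, with 399 at an unadjusted p under 0.05 (limma), at the same differences. Slide 1 held 1 mixture array and 2 levonorgestrel arrays, and slide 4 held 3 and 2, too few to read the lost calls as a smaller effect. The differences of MosFish_UF_13241 were 5.18 on slide 1 and 5.87 on slide 4, and those of MosFish_UF_15484 were 3.70 and 3.53. Female control means were -3.47 for MosFish_UF_13241 and 0.43 for MosFish_UF_15484, between the mixture and levonorgestrel means. These differences are therefore larger than the change of the mixture group from control. Against mifepristone, no probe differed in females, with 383 at an unadjusted p under 0.05 (limma).

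In males 3 probes differed between the mixture and levonorgestrel. MosFish_UF_16699 was 1.60 ± 0.31 (SD, n = 3) after the mixture and -2.45 ± 0.67 (SD, n = 4) after levonorgestrel, a log2 difference of 4.06 (SE 0.71, limma adjusted p = 0.0146). It was well above background on all 3 mixture arrays and on 1 of 4 levonorgestrel arrays. The difference was 1.56 with normexp (limma adjusted p = 0.0585), 3.81 with slide as a block (limma adjusted p = 0.0936), 3.90 without male mixture 1 (limma adjusted p = 0.144) and 3.78 without male levonorgestrel 2 (limma adjusted p = 0.0507). MosFish_UF_22867, named after its values were seen, was -3.97 ± 0.19 (SD, n = 3) and -1.98 ± 0.36 (SD, n = 4), a difference of -1.99 (SE 0.32, limma adjusted p = 0.00689). It was well above background on 1 of 3 mixture arrays and on 3 of 4 levonorgestrel arrays. The difference was -0.66 with normexp (limma adjusted p = 0.0585) and -1.96 without male mixture 1 (limma adjusted p = 0.0815). The remaining probe was MosFish_UF_12318, with 1 unflagged spot in each group, which was also the 1 probe that differed between the mixture and mifepristone in males. Without male mixture 2, one of the dimmest arrays, 166 probes differed between the mixture and levonorgestrel. With the arrays of males alone 0 probes differed, with 1009 at an unadjusted p under 0.05. The differences were the same, with adjusted p of 0.0911 for MosFish_UF_16699 and 0.316 for both MosFish_UF_22867 and MosFish_UF_12318, and against mifepristone 0.847 for MosFish_UF_12318 (limma). Slide 2 held 1 levonorgestrel array and slide 3 held 1 mixture array, too few to read lost calls there as a smaller effect. The differences on slides 2 and 3 were 4.49 and 3.65 for MosFish_UF_16699 and -1.71 and -2.21 for MosFish_UF_22867. Male control means were -0.56 for MosFish_UF_16699 and -2.82 for MosFish_UF_22867, again between the mixture and levonorgestrel means.

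**Figure D3:**
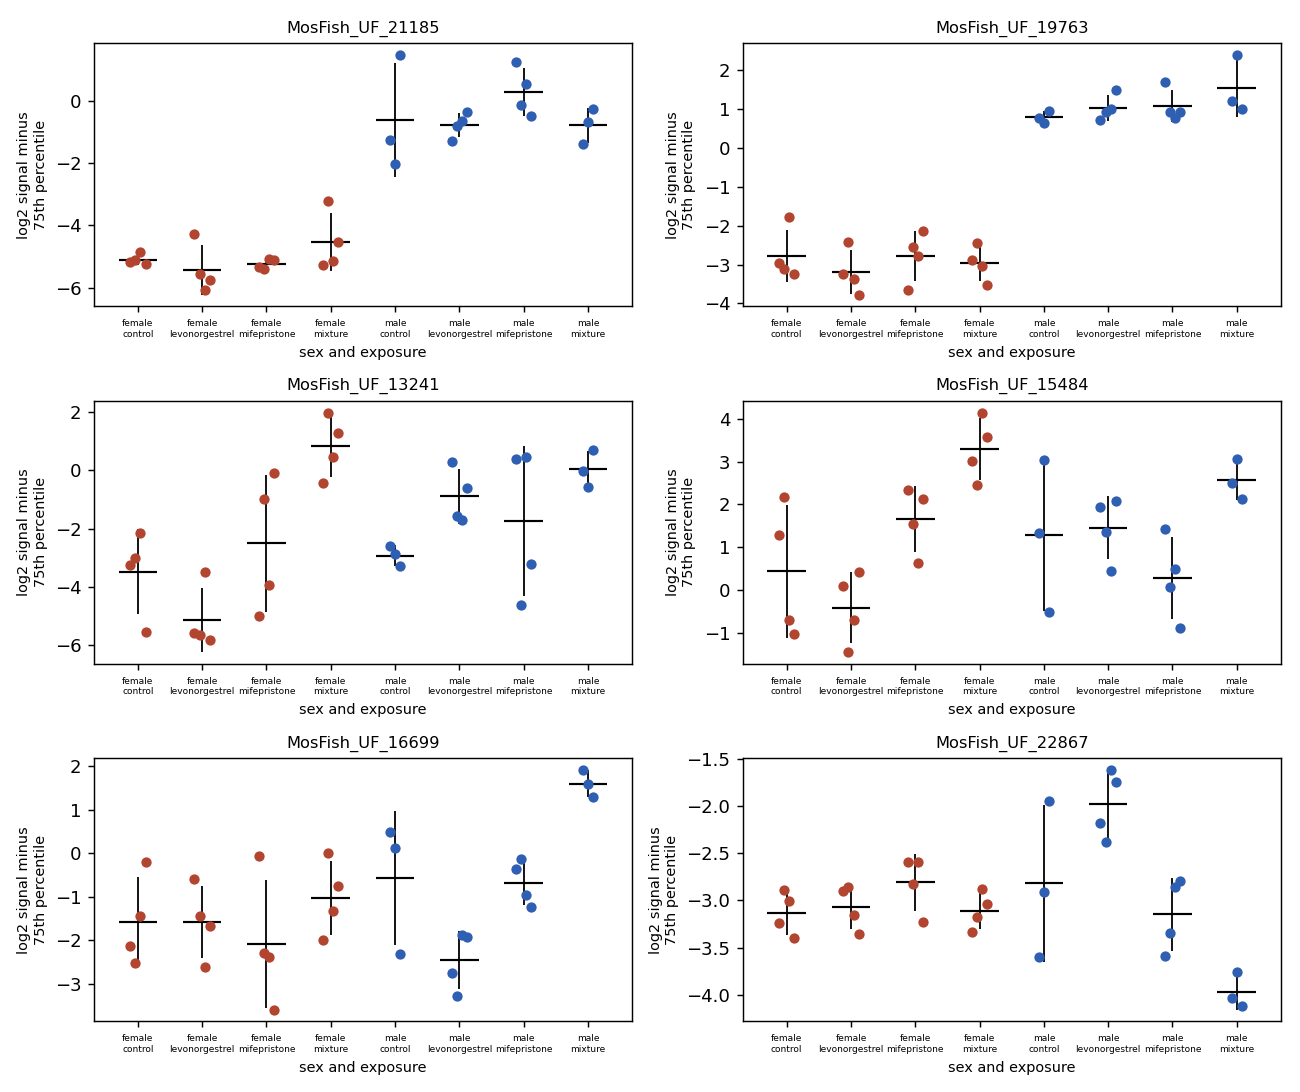
Log2 signal minus the 75th percentile of the array (vertical axes) of 6 probes in each array, by sex and exposure (horizontal axes, females red, males blue); points are arrays with unflagged spots, horizontal bars the mean and vertical bars 1 SD. MosFish_UF_19763 separates the sexes in every exposure, and MosFish_UF_13241 averages 0.82 in mixture females against -5.12 in levonorgestrel females.

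Whether the sexes responded differently was tested as an interaction. No probe passed for levonorgestrel or mifepristone, with 367 and 161 at an unadjusted p under 0.05 (limma). For the mixture 1 probe passed, again MosFish_UF_12318, with a log2 difference of 7.71 (SE 0.90, adjusted p = 0.00474). The count was 0 when at least 2 unflagged spots per group were required, with array weights and without male mixture 2, with 293, 490 and 463 probes at an unadjusted p under 0.05 (limma). The median half-width of the 95% interval was 1.44 for the single compounds and 1.5 for the mixture.

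Effects of different exposures within a sex share their control arrays, so their correlations were set against simulated unchanged groups with shared controls, across 8464 probes, which are not independent replicates. In females the correlation was 0.28 for levonorgestrel and mifepristone, 0.51 for levonorgestrel and the mixture and 0.44 for mifepristone and the mixture, each against a simulated 0.50. Their covariances were 0.078, 0.156 and 0.124, against simulated values of 0.168, 0.167 and 0.167. The simulation used each probe's spread pooled over both sexes and drew the probes independently. A covariance above or below it in 1 sex therefore cannot be read as an effect of the exposures. With a different pair of female controls for each exposure the correlations were -0.17, -0.01 and -0.07. In males the correlation was 0.53 for levonorgestrel and mifepristone against a simulated 0.57. It was 0.27 for levonorgestrel and the mixture and 0.36 for mifepristone and the mixture, both against a simulated 0.53. The male covariances were 0.216, 0.127 and 0.122 against simulated 0.225, 0.223 and 0.222, and male controls were too few to split.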

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

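The tests of scan day and of direction in exposed fish were chosen after the result was seen, and the reading of the slide test was set after its counts were seen. Dixon's test was run 62 times, on the named probes and the share above background within groups of 4 arrays. In these tests 6 values stood apart from the other 3, where independent tests would give about 3.1 by chance. The tests reused the same groups and are not independent. MosFish_UF_14675 was 1.82 in female control 4 against 9.89 to 10.44 in the others. MosFish_UF_13241 was -3.47 in female levonorgestrel 3 against -5.81 to -5.56. MosFish_UF_14833 was 9.62 in female levonorgestrel 2 against 9.11 to 9.18. MosFish_UF_12541 was -3.10 in male mifepristone 1 against 2.42 to 3.21. The share of probes well above background was 58.9% in female control 2 against 50.6% to 51.8%, and 45.7% in female mixture 3 against 56.7% to 58.8%.

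MosFish_UF_12318 differed between the sexes in its response to the mixture by 7.71 (log2). The probe was flagged on 12 of 30 arrays, and its male mixture value was 1 unflagged spot at 0.19. The flagged spots of the other 2 male mixture arrays read 5.35 and 6.40, far above 0.19. Male controls read 7.26 and 7.76 in unflagged spots and 5.40 in the flagged one, so the call rests on that one spot, and whether the probe was lower in mixture males stays open.

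The 313 probes that differed between control sexes are weighed here. Chance differences between few control fish are argued against by exposed fish, where 100% of the measured probes had the same direction, against 75% of the probes not called in controls. Mean array brightness differed little between the control sexes, with 53.2% of probes well above background in females and 54.5% in males. With that share as a covariate, 306 of the probes stayed called, but a covariate so alike in both groups could change little. Uneven brightness among the male controls is not weighed by this test and stays open. Slides differed at 278 probes among females and at 0 among males; 13 of the 278 were sex probes against 9.5 by chance, but each slide held 1 sex, so slides stay open. Scan days that held both sexes numbered 0, so scan day and sex cannot be told apart, and sex itself remains an untested biological explanation.

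Between male mixture and male levonorgestrel, 1360 probes had an unadjusted p under 0.05, where evenly spread p-values would give 458. With the covariate for brightness 1468 did and with slide as a block 1025 did, which argues against either as the whole cause. Other splits of the 7 arrays gave a median of 609.5, already above 458. Of the 35 splits, 2 including the real one gave as many as 1360, the highest other 1369, so chance stays open.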

How the results depend on the processing

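Array weights, the 2-spot rule, the other percentile, the covariate and the removal of dim arrays were chosen after seeing the data. The 3 dim arrays were all male, so their removal reached comparisons within females only through the pooled spread. Trended variances and the value table left all 16 counts within 1.5 times. The cause of the following changes was not tested. A slide held as few as 1 array of a group, and a lone array was assumed to vary like the other groups, so calls lost on a slide do not show a smaller effect.

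Female against male controls called 180 probes with normexp, 115 among probes well above background on all arrays and 185 with array weights, with 73 to 531 when an array was left out. Female mixture against levonorgestrel called 0 with quantile normalization, on slide 1 or slide 4 alone, with female arrays only and without the 3 dim arrays, 1 with no filter or the other percentile, and 5 with array weights (0 to 1 with an array left out); with normexp it called 2, of which 1 was among the 3. Male mixture against levonorgestrel called 14 with quantile normalization, 14 with array weights, 18 with the brightness covariate, 233 without the dim arrays, and 0 on slide 2 or 3 alone or with male arrays only (1 to 166); with normexp it called 3, of which 1 was among the 3. Male mixture against mifepristone called 2 with normexp, 5 on slide 2 alone, and 0 on slide 3 alone, with male arrays only, with array weights, with the 2-spot rule and without dim arrays (0 to 3). Male mixture against control called 0 on slide 2 or 3 alone, with male arrays only, with array weights, with the 2-spot rule and without dim arrays (0 to 4). Male levonorgestrel against mifepristone called 4 on slide 2 alone and 1 without dim arrays (0 to 6). Female levonorgestrel against mifepristone called 3 with array weights. Female mixture against mifepristone called 1 among probes well above background on all arrays. Male mifepristone against control called 1 without dim arrays (0 to 1). Male levonorgestrel against control called 0 to 5 with an array left out. The sex difference in the response to the mixture called 0 with array weights, the 2-spot rule and without dim arrays (0 to 2), and that to levonorgestrel 0 to 1. Remaining comparisons called 0 with any array left out.

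The replicate numbers do not pair the samples: correlations of same-numbered deviations ran from -0.25 to 0.44, and 11 of 30 arrays correlated best with their own number. With the replicate number as a block, the sex difference in the response to the mixture called 0 probes; no other count moved by over 1.5 times, and female against male controls called 283.

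With a different pair of female controls for each exposure, correlations of effects turned from 0.28 to -0.17 for levonorgestrel and mifepristone, from 0.51 to -0.01 for levonorgestrel and mixture, and from 0.44 to -0.07 for mifepristone and mixture; the shared controls had added to the unsplit values. Gene list alternatives were not run, since no probe had a gene name.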

Other observations

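Other splits of the same arrays show how far chance can be excluded. Each number of splits given here includes the real one. For female against male controls, 1 of 35 splits (the real one) called as many as 313 probes, the highest other 124. For female mixture against levonorgestrel 1 of 35 called as many as 3, the highest other 2. In each case the share was 1 of 35, the smallest possible. It is not adjusted over the 16 comparisons, so by itself it does not exclude chance for either count. The real split of the control sexes also separates slides and scan days. The margin of 3 against 2 is narrow, and that count was 0 or 1 without any 1 array and 0 with quantile normalization. The counts at an unadjusted p under 0.05 do not exclude chance either. Between control sexes 3 of 35 splits gave as many as 1597 (highest other 1747). Between female mixture and levonorgestrel 15 of 35 gave as many as 312 (highest other 962). For male mixture against levonorgestrel 19 of 35 splits called as many as 3 (highest other 42), and against mifepristone 9 of 35 as many as 1 (highest other 53). The sex difference in the response to the mixture called 1, and 42 of 100 splits, the real one among them, called at least 1 (highest other 231). Male mixture against control allows 10 splits, too few for a share under 0.05. It called 1 probe, 7 splits including the real one called at least 1, and the highest other called 75.

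Where the real count was 0, all 35 splits give as many by construction, which says nothing about chance. Their highest other counts were 1, 2 and 15 for female levonorgestrel, mifepristone and mixture against control, 89 and 20 for male levonorgestrel and mifepristone, 3 for female mixture against mifepristone, and 1 and 8 for levonorgestrel against mifepristone in females and males. For the sex difference in the response to levonorgestrel and mifepristone, all 100 drawn splits likewise give as many, with highest others of 9 and 379. Why some splits call several times the real count was not tested.

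One hypothesis was that exposure moved the liver toward the pattern of the other sex. An index (mean of female-higher minus mean of male-higher probes, log2) was built from the arrays of the 2 exposures not compared, and 6 comparisons were tested by exact two-sided permutation. After levonorgestrel the male index was 2.26 ± 0.53 (SD, n = 4) against 1.03 ± 0.73 (SD, n = 3) in male controls and 3.78 in female controls, a difference of 1.23 (exact permutation p = 0.0857, adjusted p = 0.513). This is in the direction of the hypothesis but did not pass. The other male differences were 0.23 after mifepristone and 0.11 after the mixture. In females the differences were 0.43, 0.15 and -0.04 after levonorgestrel, mifepristone and the mixture. A move toward the other sex is negative in females, so 0.43 and 0.15 lie away from the male pattern, against the hypothesis. The exact permutation p of these other differences ran from 0.171 to 0.9. The smallest p the design allows is 0.0286 with 4 against 4 or 4 against 3 arrays and 0.1 with 3 against 3.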
